A study of Homo sapiens with 10 samples.

How the data were processed

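CUT&RUN maps where a protein or a histone mark sits on DNA: an antibody brings a nuclease to its target in permeabilised cells, and the released fragments are sequenced. The libraries came from GI-MEN, an established human neuroblastoma cell line. Per the labels, all cells overexpressed a set of 4 transcription factors (the labels used here do not name them), either alone or together with ASCL1, a proneural basic helix-loop-helix factor, and were collected after DMSO or doxycycline. Per the labels' protocols, about 500000 cells went into each reaction and about 10000000 paired-end reads of 150 bp were ordered per library. The series used here holds 10 samples. A peak list was available for 7 of them: H3K27ac (an acetylation mark of active promoters and enhancers), MYCN and PHOX2B, each without and with ASCL1, and HA with ASCL1. HA is an epitope tag. The sample title gives ASCL1 as the target of the HA library, and the labels do not say whether another factor in these cells carried the tag. The 3 IgG control samples, 2 with ASCL1 and 1 without, were not analysed here.

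The deposited files are peak lists, called by the authors separately for each sample. Each list has 4 columns (chromosome, start, end and peak name), per the file contents. The submitters' processing notes name MACS2, SEACR and the genome build hg19 without saying which step each served, and the peak names and file types follow MACS2's narrow peak format for HA, MYCN and PHOX2B and its broad peak format for H3K27ac. The threshold, the control library, the duplicate handling and the aligner are not given in the sources used here. The deposited lists hold no score, fold enrichment, p-value, q-value or summit, so peaks could not be ranked by strength, and peak width in bp was the only size available. The read depth behind each list is unknown, which means that a peak missing from a list was not called at that depth and is not shown to be absent. Peak numbers ran without a gap in every list, so no peak was missing between the first and the last number. Removal of peaks at either end of the numbering, or before a renumbering, would not show. Peak ends exceeded the GRCh38 chromosome lengths on 11 to 15 chromosomes per list and exceeded no hg19 length, so coordinates are given as hg19, counted from 1.

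No hg19 sequence or gene annotation was used here, and coordinates were not converted from another build. Regions are therefore named by position, and the planned counts at transcription start sites, in gene lists and in sequence motifs were not run. The planned ranking of named regions by q was replaced by a ranking by width, chosen after seeing that the files give no q: the 10 widest regions found only with ASCL1, the 10 widest found only without, the 5 widest shared regions of each target, and the 15 widest HA peaks.

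Peaks on chromosomes 1 to 22 and X were used. For each target, the peaks of both treatments were merged into regions where they overlapped by at least 1 bp, and each region was classed as shared, only with ASCL1 or only without ASCL1. Shares of regions or peaks that overlap another list carry Wilson 95% intervals, differences between classes Newcombe intervals, and changes at the same peaks Wald intervals for paired shares. These intervals cover counting error only. There was 1 library per target and treatment, so no test between treatments was made and no p-value is given. Neighbouring regions are not independent replicates. HA peaks were also placed 100 times at random positions of their own chromosome, and 100 times at positions moved by 10 to 50 kb, to give the overlap expected from list size and from neighbourhood. To compare classes at equal width, regions were sampled to the same numbers in 10 width bins, and the mean of 100 draws was taken. The change of H3K27ac was also counted as bp under peaks in windows of 10 kb. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

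The overlap code was tested on simulated lists with the widths of the real peaks and planted sharing. It recovered 100% of 28432 planted shared regions among 118743 regions for the H3K27ac comparison. Recovery was also 100% of 4922 among 23955 for MYCN and 100% of 1302 among 6756 for PHOX2B. Each planted pair or single peak stood apart from all others, so the merging of clustered peaks was not tested. Before the data were examined, the plan fixed the region classes and their HA share. It also fixed the overlap of HA peaks with each target and of MYCN with PHOX2B. Splits of HA peaks by MYCN or PHOX2B and the sorting of sites by factor were not planned. Nor were the moved HA positions, the windows of 10 kb, the domains and the counts by chromosome. The overlap rule and 4 of the 8 alternatives that were run were fixed in advance: an overlap of at least 50% of the shorter interval, all contigs, merging of peaks within 500 bp, and matching on width. The other 4 were added after seeing that the lists hold no scores or summits: peaks of at least 200 bp, equally long lists made of the widest peaks, windows of 250 bp to each side of the peak midpoint, and lists without 1 Mb bins that hold peaks of 1500 bp or more in at least 3 of the HA, MYCN and PHOX2B lists.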

Results

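The 7 peak lists differed in length by target. H3K27ac gave 76094 broad peaks without ASCL1 and 71081 with it, with median widths of 261 and 322 bp and 31.8 and 33.7 Mb covered. MYCN, the oncogenic bHLH transcription factor of high-risk neuroblastoma, gave 16572 narrow peaks without ASCL1 (median 317 bp, 6.72 Mb) and 12305 with it (248 bp, 3.92 Mb). PHOX2B, the homeobox factor of the noradrenergic lineage, gave 4802 peaks without ASCL1 (187 bp, 1.11 Mb) and 3256 with it (207 bp, 0.857 Mb). HA, which marked the tagged protein in cells with ASCL1, gave 21607 peaks (232 bp, 6.36 Mb). There was 1 library per target and treatment, so each difference below compares 2 libraries and has no replicate check.

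The first comparison asked where the HA-tagged protein lay in cells with ASCL1 and what already occupied those places in cells without it. HA peaks fell into 2 parts of similar size. In the first part, 10303 HA peaks (47.7% of all) overlapped a MYCN peak of the cells without ASCL1, and 95.8% of them (Wilson 95% interval 95.4 to 96.2) already overlapped H3K27ac in those cells. In the second part, 11304 HA peaks (52.3%) had no MYCN peak in cells without ASCL1, and 40.0% of these (39.1 to 40.9) overlapped H3K27ac there. PHOX2B of the cells without ASCL1 lay at 2749 HA peaks (12.7%), of which 93.1% (92.1 to 94.0) overlapped H3K27ac. HA peaks moved by 10 to 50 kb overlapped the MYCN, PHOX2B and H3K27ac lists without ASCL1 in 1.23%, 0.354% and 4.74% of cases on average, against 47.7%, 12.7% and 66.6% in place.

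H3K27ac was called at HA peaks more often with ASCL1 than without. Of the 21607 HA peaks, 14387 (66.6%, 66.0 to 67.2) overlapped H3K27ac without ASCL1 and 15901 (73.6%, 73.0 to 74.2) with it, a difference of 7.01 percentage points (6.47 to 7.55). An H3K27ac peak was found only with ASCL1 at 2590 HA peaks and only without at 1076, a ratio of 2.41. Over all H3K27ac regions, the number found only with ASCL1 divided by the number found only without was 0.890 as called. Peaks of at least 200 bp gave the other order, with 22950 only with and 20763 only without, and equally long lists, which draw the numbers together by construction, gave 38865 and 38638. The difference lay in the HA peaks without MYCN, where the share went from 40.0% to 53.9% (52.99 to 54.8), with 2350 peaks marked only with ASCL1 and 773 marked only without. At HA peaks with MYCN it went from 95.8% to 95.2%, with 240 marked only with ASCL1 and 303 only without. This class started near its ceiling, since only 433 of its peaks were unmarked without ASCL1, and 55.4% of those were marked with it, against 34.6% of the 6787 unmarked peaks in the other class. Among the 10304 HA peaks that overlapped MYCN and PHOX2B in no list of either treatment, the share went from 37.6% to 51.8%, a difference of 14.3 points (13.3 to 15.2).

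**Figure D1:**
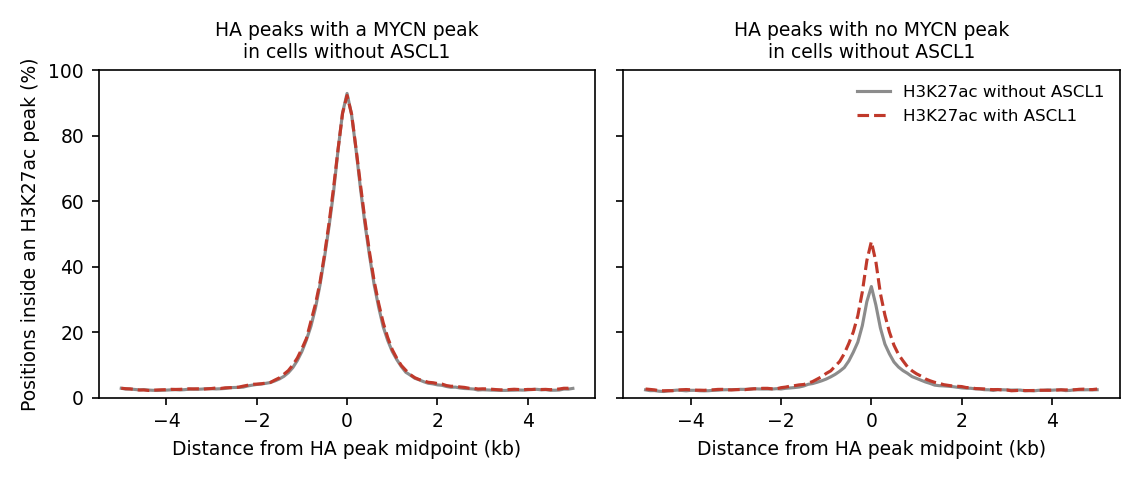
Share of positions inside an H3K27ac peak (y axis, %) by distance from the midpoint of HA peaks (x axis, kb), for the 10303 HA peaks with a MYCN peak in cells without ASCL1 (left) and the 11304 without one (right). Solid grey lines are the H3K27ac library without ASCL1 and dashed red lines the library with ASCL1. At the midpoint the left curves reach 92.9% and 92.3%, and the right curves 34.0% without and 47.7% with ASCL1.

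The second comparison set the H3K27ac lists of both treatments side by side. Merging gave 113531 regions, of which 32348 (28.5%) were shared, 38220 (33.7%) were found only with ASCL1 and 42963 (37.8%) only without. Shared regions were wide (median 744 bp), and those found in a single treatment were narrow (200 bp only with ASCL1 and 174 bp only without). HA peaks lay in 38% of shared regions (37.5 to 38.5), in 5.39% of regions only with ASCL1 (5.17 to 5.62) and in 1.88% of regions only without (1.76 to 2.02). The last 2 differed by 3.51 points (3.25 to 3.77). MYCN peaks of the cells without ASCL1 had the opposite order, at 0.913% of regions only with ASCL1 (0.823 to 1.01) and 1.32% of regions only without (1.21 to 1.43). MYCN peaks of the cells with ASCL1, the cells of the HA list, were at 0.659% (0.583 to 0.746) and 0.766% (0.688 to 0.853), intervals that overlap. PHOX2B peaks of the cells without ASCL1 were at 0.594% (0.522 to 0.676) and 0.633% (0.562 to 0.713), intervals that overlap, and PHOX2B peaks of the cells with ASCL1 at 0.638% (0.563 to 0.723) and 0.310% (0.261 to 0.367).

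Of the 10 widest H3K27ac regions found only with ASCL1, 4 held an HA peak, and of the 10 widest found only without, 1 did. The widest of the first kind lay on chromosome 12 from 111882592 to 111885188 (2597 bp) and on chromosome 6 from 33712535 to 33714760 (2226 bp). Both held HA and had no MYCN or PHOX2B peak in either treatment. The other 2 with HA lay on chromosome 9 from 137568357 to 137570265 and on chromosome 19 from 1312442 to 1314292, the latter also with a MYCN peak in cells with ASCL1. The widest region found only without ASCL1 lay on chromosome 6 from 170966773 to 170968829 (2057 bp) and held no peak of HA, MYCN or PHOX2B. The single region of this kind with HA, on chromosome 9 from 130323830 to 130325664, also held MYCN in cells without ASCL1. The 5 widest shared regions were led by chromosome 16 from 46403600 to 46409080, which held a peak in all 7 lists.

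**Figure D2:**
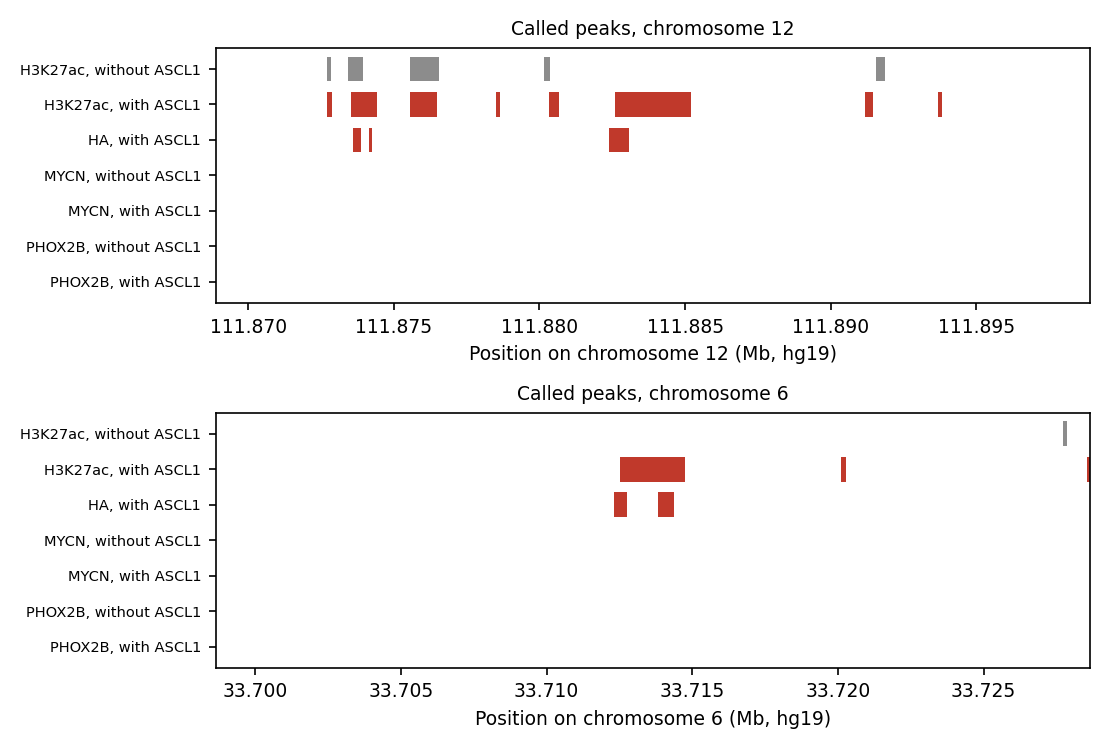
Called peaks (boxes) of the 7 lists over 30 kb around the 2 widest H3K27ac regions found only with ASCL1, on chromosome 12 (top) and chromosome 6 (bottom), with hg19 position in Mb on the x axis and 1 row per list. Grey boxes are lists without ASCL1 and red boxes lists with ASCL1. The wide H3K27ac peaks of 2597 and 2226 bp stand in the second row only, with HA peaks in the third row at the same place and no MYCN or PHOX2B peak in the window.

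The third comparison concerned MYCN. Of the 18547 MYCN regions, 9487 (51.2%) were shared, 6939 (37.4%) were found only without ASCL1 and 2121 (11.4%) only with it. Most MYCN peaks of the cells with ASCL1 were already there without it (82.8%, 82.1 to 83.4), whereas 58.1% (57.4 to 58.9) of the peaks without ASCL1 were found again. Equally long lists of the widest peaks, which draw the 2 numbers together by construction, gave 3691 regions only without ASCL1 and 3069 only with it. Peaks of at least 200 bp set them further apart in proportion, with 4864 only without and 632 only with. As called, shared regions had a median width of 532 bp, against 189 bp for regions only without ASCL1 and 127 bp for regions only with it. At shared regions the MYCN peak was narrower with ASCL1, with a median ratio of widths of 0.744 (bootstrap 95% interval 0.736 to 0.752).

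HA peaks lay in 80.6% of shared MYCN regions (79.8 to 81.4), in 33.4% of regions only without ASCL1 (32.3 to 34.6) and in 26.0% of regions only with ASCL1 (24.2 to 27.9). The last 2 differed by -7.42 points (-9.56 to -5.22) as called. After sampling to equal widths the difference was 0.297 points (-2.47 to 3.06). With windows of 250 bp to each side of the peak midpoint it was -10.4 points (-12.8 to -7.87). Neighbouring windows were merged into wider regions, and HA peaks were also made windows, so this value does not hold width strictly equal. The interval of the value from sampling to equal widths spans no difference. HA peaks that overlapped MYCN numbered 10303 without ASCL1 and 8346 with it, a change of -9.06 points that was -2.84 points with equally long lists. H3K27ac stood at 96.8% of shared MYCN regions without ASCL1 and at 96.1% with it. At MYCN regions found only with ASCL1, it was 53.6% (51.4 to 55.7) without and 52.0% (49.9 to 54.1) with ASCL1. The widest MYCN region found only without ASCL1 lay on chromosome 1 from 112162283 to 112163283 (1001 bp) and the widest found only with ASCL1 on chromosome 10 from 102757825 to 102758363 (539 bp). The 10 widest of each kind held HA in 6 and in 8 cases. The 5 widest shared MYCN regions held a peak in all 7 lists, led by chromosome 6 from 58776240 to 58779458. All 5 lay in the 1 Mb bins with wide peaks in several lists that an alternative leaves out, as did the 5 widest shared PHOX2B regions, 2 of the 5 widest shared H3K27ac regions and 6 of the 15 widest HA peaks. No IgG library and no list of artefact-prone regions was used here, so a peak in all 7 lists does not by itself show shared binding.

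**Figure D3:**
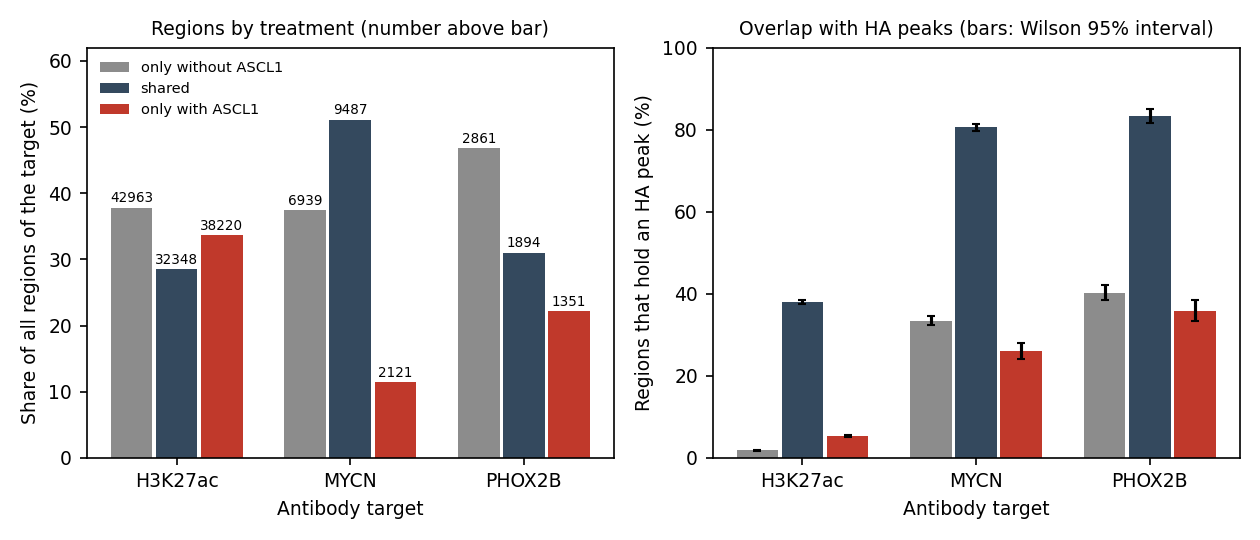
Regions of each target (x axis) found only without ASCL1 (grey), in both treatments (dark blue) and only with ASCL1 (red): share of all regions of the target in % with the number above each bar (left), and share that holds an HA peak in % with Wilson 95% intervals (right). HA peaks lie in 80.6% of shared MYCN and 83.4% of shared PHOX2B regions, and in 5.39% against 1.88% of the H3K27ac regions found only with and only without ASCL1.

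The fourth comparison concerned PHOX2B. Of the 6106 PHOX2B regions, 1894 (31.0%) were shared, 2861 (46.9%) were found only without ASCL1 and 1351 (22.1%) only with it. Equally long lists of the widest peaks gave 1658 only without and 1679 only with, again drawn together by construction. HA peaks lay in 83.4% of shared regions (81.6 to 85.0), in 40.2% of regions only without ASCL1 (38.4 to 42.0) and in 35.9% of regions only with ASCL1 (33.4 to 38.5), the last 2 differing by -4.33 points (-7.43 to -1.18). After sampling to equal widths this difference was -4.79 points (-8.43 to -1.12). With windows of 250 bp to each side of the peak midpoint it was -0.456 points (-3.78 to 2.89). With equally long lists made of the widest peaks it was 0.340 points, of the opposite sign. Unlike the MYCN regions, PHOX2B regions found only with ASCL1 overlapped H3K27ac more often with ASCL1 than without, at 49.8% (47.2 to 52.5) against 40.4% (37.8 to 43.1). Those found only without ASCL1 did so at 58.4% with and 59.8% without. Of PHOX2B peaks, 56.9% (55.4 to 58.2) overlapped MYCN in cells without ASCL1 and 52.1% (50.4 to 53.8) in cells with it. Of MYCN peaks, 16.3% (15.8 to 16.9) without and 14.1% (13.4 to 14.7) with ASCL1 overlapped PHOX2B. This order turned with peaks of at least 200 bp (11.8% without and 12.4% with ASCL1). Both lists were shorter with ASCL1, which by itself can lower overlap. With equally long lists of the widest peaks, the MYCN shares were 14.9% without and 14.1% with ASCL1.

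The widest PHOX2B regions found only with ASCL1 lay on chromosome 2 from 56354443 to 56355275 (833 bp), where H3K27ac was called only with ASCL1, and on chromosome 5 from 118753851 to 118754652 (802 bp), where it was called only without. Of the 10 widest of this kind, 5 held HA, 5 overlapped H3K27ac without ASCL1 and 8 with it. On chromosome 7, the region from 96723866 to 96724452 had HA, and H3K27ac with ASCL1 only. The widest region found only without ASCL1, on chromosome 4 from 40256737 to 40257722 (986 bp), held HA, and H3K27ac only without ASCL1. The 5 widest shared PHOX2B regions, like 11 of the 15 widest HA peaks, held a peak in all 7 lists. These HA peaks were led by chromosome 6 from 58776244 to 58779527 (3284 bp) and chromosome 21 from 9825458 to 9827569 (2112 bp), and 1272 of 120928 merged regions overall had a peak in every list.

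The last comparison sorted the 26305 sites bound in cells with ASCL1 by the factors that had a peak there. HA alone held 12830 sites, HA with MYCN 6369, MYCN alone 3877, all 3 factors 1636, PHOX2B alone 1118, HA with PHOX2B 404, and MYCN with PHOX2B 71. H3K27ac differed most between treatments at HA with PHOX2B, where it stood at 55.2% of sites without ASCL1 and 75.7% with it, a difference of 20.5 points (15.3 to 25.8). These sites were called in cells with ASCL1 and lack MYCN. At all HA peaks with PHOX2B of the cells without ASCL1 the change was 0.364 points (-0.634 to 1.36). That set started near its ceiling, at 93.1% marked without ASCL1, so it could not show a rise of that size. Of its 189 unmarked peaks, 54.5% were marked with ASCL1. At HA alone the difference was 11.3 points (10.5 to 12.2), and at PHOX2B alone 7.78 points (4.80 to 10.8). It was -0.361 points (-0.862 to 0.140) at HA with MYCN and -0.428 points (-1.49 to 0.637) at all 3 factors, where H3K27ac already stood at 96.2% and 96.3% of sites without ASCL1. At MYCN alone it was -2.27 points (-3.39 to -1.15), and at the 71 sites of MYCN with PHOX2B -5.63 points (-17.3 to 6.0).

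**Figure D4:**
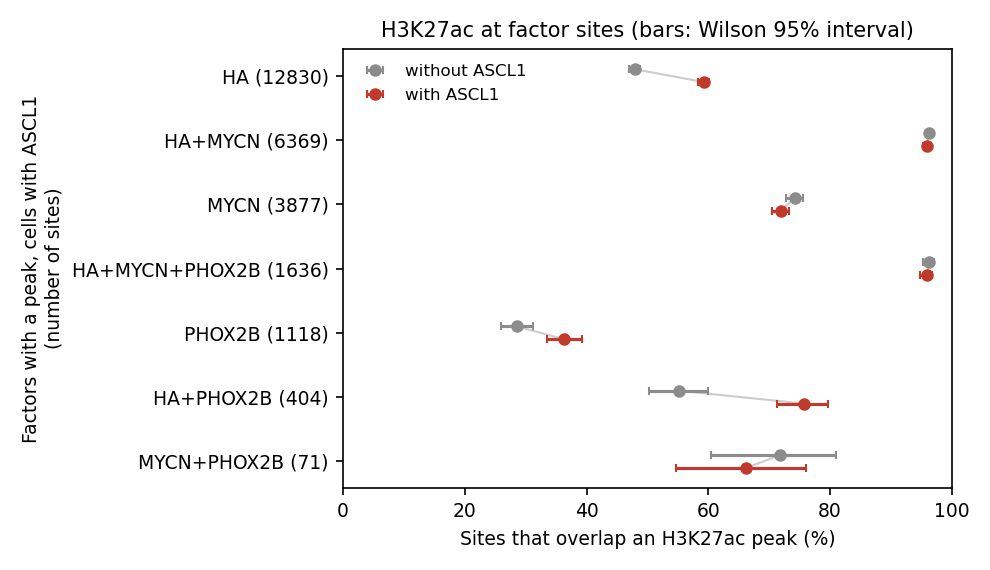
Share of factor sites that overlap an H3K27ac peak (x axis, %) without ASCL1 (grey points) and with ASCL1 (red points), for the 7 combinations of factors called in cells with ASCL1 (y axis, number of sites in parentheses); bars are Wilson 95% intervals. HA with PHOX2B moves from 55.2% to 75.7% and HA alone from 47.9% to 59.2%, while HA with MYCN stays near 96%.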

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

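Peaks on the mitochondrial genome lay outside the chromosomes used above and were noticed only after the lists had been read. They numbered 11 in the HA list, 7 and 6 in the H3K27ac lists without and with ASCL1, 7 and 8 in the MYCN lists, and 9 and 11 in the PHOX2B lists, all above the 3 that a count of 0 allows. No explanation was tested.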

How the results depend on the processing

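The settings on peaks of at least 200 bp, the widest N peaks, midpoint windows and 1 Mb bins were chosen after seeing the data. Of 166 values of 25 results recomputed under 8 alternatives, 108 stayed within the counting interval or within 1.5 times the count. Another 55 left it, and 3 differences changed sign. Counts and shares have no sign, so an order of counts or shares that turned is not among the 3. The cause was not tested except where the alternative itself removes peaks. The rise of H3K27ac at HA peaks and the excess of HA in H3K27ac regions only with ASCL1 kept their direction under every alternative run. Using all contigs, or leaving out 7 bins of 1 Mb with wide peaks in several lists, moved none of the 25 results. Percentages and points below are in the order H3K27ac, MYCN, PHOX2B where several are given.

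The signs that changed were the MYCN difference in HA share between regions only with and only without ASCL1, at 0.297 points when matched on width, and with the widest N peaks the PHOX2B difference, at 0.340, and the change of PHOX2B at HA peaks, at 0.106 points instead of -2.98. The order of H3K27ac regions only with and only without ASCL1 also turned with peaks of at least 200 bp, to 22950 and 20763. The other values that moved follow by setting. With 50% of the shorter interval, HA was in 4.91% of H3K27ac and 32.2% of PHOX2B regions only with ASCL1, the differences were 2.98 points for H3K27ac and -3.42 for MYCN, HA peaks overlapped the 3 targets with ASCL1 in 70.1%, 36.5% and 9.02%, MYCN changed by -8.56 points at HA peaks, and MYCN peaks overlapped PHOX2B in 13.1% with and 15.5% without ASCL1. Merging within 500 bp gave HA in 23.3% of MYCN regions only with ASCL1 and a difference of -12.7 points. Width matching gave 5.0% for H3K27ac and 3.02 points. Peaks of at least 200 bp left 12674 HA peaks, 22950 and 20763 H3K27ac regions only with and only without ASCL1, 632 MYCN regions only with, and 751, 1183 and 966 PHOX2B regions only with, only without and shared. There, HA was in 5.77%, 36.1% and 40.2% of regions only with ASCL1, the differences were 4.01 points for H3K27ac and -0.663 for MYCN, HA peaks overlapped the targets in 81.1%, 41.0% and 8.78%, their changes were 8.35, -12.7 and -1.88 points and 18.5 points for H3K27ac at HA peaks without MYCN, and MYCN peaks overlapped PHOX2B in 12.4% with and 11.8% without ASCL1, the reverse of the order in the full lists. The widest N peaks gave 3691 MYCN and 1658 PHOX2B regions only without ASCL1 (3069 and 1679 only with it, numbers that equal lists draw together by construction), HA in 39.6% of MYCN and 44.6% of PHOX2B regions only with, a MYCN difference of -1.94 points, changes at HA peaks of 7.56 points for H3K27ac and -2.84 for MYCN, and 14.9% of MYCN peaks with PHOX2B without ASCL1. Midpoint windows gave HA in 5.84%, 28.3% and 43.0% of regions only with ASCL1, differences of -10.4 for MYCN and -0.456 for PHOX2B, overlaps of HA peaks of 75.2%, 40.4% and 10.6%, changes of -8.41 for MYCN and 14.9 for H3K27ac at HA peaks without MYCN, and 15.3% and 17.8% of MYCN peaks with PHOX2B with and without ASCL1.

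A threshold of 5 on the -log10 q scale, equal lists ranked by q, summit windows and the settings for transcription start sites, gene loci and motifs were not run, since the lists give no q or summit and no hg19 annotation or sequence was used here. No paired analysis was possible because each target has 1 library per treatment. Unknown depth limits every count of regions found in a single treatment.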

Other observations

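The tests on open chromatin, on overall H3K27ac calling, on displacement at HA peaks, on copies of chromosome 18 and on HA peaks per 100 kb of domain were chosen only after the result they address was seen, and the windows and the domain named below were chosen after their values were seen. Counted as bp under peaks, windows that gained or lost H3K27ac differed in the factors present. Of 78673 windows of 10 kb that held H3K27ac in either treatment, 1404 had at least 1000 bp more with ASCL1, and 40.8% of these (38.3 to 43.4) held an HA peak, while 501 had at least 1000 bp less and 29.3% (25.5 to 33.5) held an HA peak. Both lay above the 19.1% (18.8 to 19.4) of windows that changed by under 500 bp. MYCN of the cells without ASCL1 went the other way, with 17.7% (15.8 to 19.7) of the first kind and 34.5% (30.5 to 38.8) of the second. It was at 16.7% of the 65262 windows that changed by under 500 bp. Only windows with at least 1000 bp of H3K27ac in either treatment can change that much, and windows were not matched on cover. No conclusion is therefore drawn, for HA or MYCN, from the comparison with windows that changed by under 500 bp. Of the 10 windows with the largest gain, 6 held HA and 1 held MYCN of the cells without ASCL1, and of the 10 with the largest loss 3 and 5 did. The window on chromosome 2 from 165760001 to 165770000 had no H3K27ac without ASCL1, 2146 bp with it, 879 bp of HA peaks, and a PHOX2B peak of 330 bp with ASCL1 only, which no other of the 10 largest gains with HA held. The window on chromosome 11 from 118780001 to 118790000 had 3343 bp without ASCL1 and 1251 bp with it, and its MYCN peaks covered 451 bp without and 215 bp with ASCL1, beside 434 bp of HA peaks.

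Dense H3K27ac domains were also compared. Peaks at most about 12 kb apart were joined, and the 500 domains with the most covered bp were taken from each treatment. Of the 500 domains with ASCL1, 194 overlapped no top domain of the other treatment, and 94.8% of these (90.8 to 97.2) held an HA peak. Of the domains without ASCL1, 175 overlapped no top domain with ASCL1, and 94.9% of these (90.5 to 97.3) held an HA peak. A domain outside the other top list can still hold H3K27ac in that treatment. Nearly every top domain of either treatment held an HA peak, so these shares cannot show whether the classes differ. HA peaks per 100 kb were fewer in the domains only in the top list with ASCL1, at 4.31 (3.87 to 4.81). Those only in the top list without ASCL1 had 5.60 (4.97 to 6.36), a difference of -1.29 (bootstrap 95% interval -2.14 to -0.475). The domains only in the top list with ASCL1 were also longer, with median spans of 82.8 against 62.7 kb. The median was 3 HA peaks in both classes, so the lower density does not show fewer HA peaks per domain. Among domains only in the top list with ASCL1, the largest difference in cover was on chromosome 2 from 236837304 to 237051966, with 16106 bp against 7667 bp and 2 HA peaks.

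H3K27ac was more frequent at HA peaks with ASCL1 than without (73.6% against 66.6%). More H3K27ac calling in the whole library is argued against in part by sites that lack HA and start near the 40.0% of HA peaks without MYCN. The share changed by -1.07 points (-3.21 to 1.06) from 40.3% at PHOX2B peaks of the cells without ASCL1. It changed by -3.19 points (-5.40 to -0.972) from 45.6% at MYCN regions called only with ASCL1. The -2.89 points (-3.85 to -1.94) at MYCN peaks of the cells without ASCL1 that lack HA weigh little, since these started at 81.5%, and 34.5% of their unmarked peaks were marked with ASCL1, against 34.6% at HA peaks without MYCN. PHOX2B peaks called with ASCL1 that lack HA rose by 6.46 points (3.58 to 9.34), so a rise limited to such sites is not excluded. Wider regions are also argued against, but only for regions found in a single treatment. The difference of HA share between regions only with and only without ASCL1 was 3.02 points (2.75 to 3.28) at equal widths. Shared regions were not part of that comparison, so wider shared peaks that newly reach an HA peak are not excluded. Cutting of chromatin that is open in the same cells, whatever the antibody, may contribute and cannot be told apart from ASCL1 binding: regions called only with ASCL1 and lacking HA gained 7.85 points (4.49 to 11.2) for PHOX2B but not for MYCN, as above, H3K27ac was most often called at the HA midpoint itself, and the IgG libraries were not analysed here. Acetylation at sites that ASCL1 occupies stays open as the biological hypothesis, from 1 library per treatment.

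The MYCN and PHOX2B lists were shorter with ASCL1, at 0.743 and 0.678 of their length without it. For MYCN, a weaker signal in the library with ASCL1 is a candidate explanation, since at shared regions its peaks were 0.744 times as wide as without ASCL1, with 0.758 (0.749 to 0.765) where HA lay and 0.683 (0.662 to 0.707) where it did not. For PHOX2B the ratio was 1.01 (1.0 to 1.02), which argues against narrower peaks as a sign of weaker signal, although width says nothing of peaks that were lost. The losses were not concentrated at HA peaks. At equal width, MYCN peaks with HA were found again 28.9 points (27 to 30.7) more often than those without, and PHOX2B peaks 33.2 points (30.3 to 36) more often. HA peaks and the peaks found again were called in the same cells with ASCL1, so a site that closed there would hold neither. These values therefore cannot decide on displacement by HA. Displacement, lower levels of either factor, a difference in depth and a loss of binding stay open.

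H3K27ac peaks on chromosome 18, the chromosome with the lowest ratio of the 23 examined, numbered 1451 without ASCL1 and 1133 with it, a ratio of 0.781 against 0.937 on the others. The other chromosomes also varied, from 0.857 on X to 1.02 on chromosome 17. Cover under H3K27ac peaks on chromosome 18 went from 0.530 Mb without ASCL1 to 0.494 Mb with it. Chromosome 18 also had the fewest HA peaks per Mb (2.69), and a link of HA density with the ratio was not tested. A fall in a few places is argued against, since 15 of its 16 bins of 5 Mb lay below the genome-wide ratio. Fewer copies of the chromosome in the cells with ASCL1 may contribute and cannot be told apart from a change of the mark: relative to the other chromosomes, the number of MYCN peaks on it was 1.05 times (0.863 to 1.28) and of PHOX2B peaks 0.767 times (0.511 to 1.15), against 0.833 (0.770 to 0.901) for H3K27ac. The PHOX2B value rests on 36 and 69 peaks.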
